A study of Mus musculus with 4 samples.

How the data were processed

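Single-cell RNA libraries were made from limb bone marrow of C57BL/6 mice at postnatal day 12. Per the labels, live cells negative for the blood markers CD45 and Ter119 were sorted from 3 control mice and 3 Prx1-cre;Mettl3-fl/fl mice, and droplet 3′ libraries were prepared with 10x Genomics reagents. Prx1-cre is active in the limb mesenchyme, and Mettl3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The series holds 4 libraries, 2 per genotype; how the mice map to the libraries is not given in the sources used here, so p-values measure the spread between these libraries, part of which may be technical. Replicate numbers follow the order of deposition and only name a library. The label of mutant 2 gives the genotype only as mutant.

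The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization, per the file headers. Per the submitters' processing notes, reads were processed with Cell Ranger and the mm10 build, with version 5.0.1 for control 1 and mutant 1 and version 6.1.2 for control 2 and mutant 2. The matrix headers differ from this: they name Cell Ranger 4 for control 1, control 2 and mutant 2, and version 5.0.1 for mutant 1. The split used here rests on the notes alone and puts 1 library of each genotype in each of 2 processing batches, called batch 1 and batch 2 here. The annotation used for counting is not given in the sources used here. The deposited counts of control 1, control 2 and mutant 2 cover all barcodes, while those of mutant 1 cover a list of 3352 called barcodes with at least 501 UMIs each. The 32285 gene identifiers were the same in all libraries, and 32158 of them were found in GENCODE M21, which supplied positions on mm10. Near-identical gene copies (Bglap and Bglap2, Hspa1a and Hspa1b, the Stfa and Cstdc genes, the globin genes) can share reads, so the split of their counts is uncertain.

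One rule was applied to every library: at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored with Scrublet as implemented in scanpy 1.11.5, and the top 0.8% per 1000 cells was removed, which took 270 cells from control 1, 106 from control 2, 55 from mutant 1 and 168 from mutant 2. Log-normalized values of 2000 variable genes were centred per processing batch, never per genotype, reduced to 30 principal components and joined over 15 neighbours, and Leiden clustering at resolution 1 (leidenalg 0.10.2) gave 35 clusters over 16059 cells. Clusters were named from marker lists fixed for 18 classes. A cluster needed at least 3 detected markers of its class, and no more of another class than of its own among its 10 leading genes. A cluster with low UMI counts for its libraries also needed at least 1 marker of its class among those 10 genes. That rule left clusters 6 and 26 unnamed, with 794 and 105 cells and erythroid markers. A marker counted as detected in a cluster when at least 25% of its cells held it and its level reached 10% of that in the highest cluster of at least 50 cells; these detection thresholds were set after marker levels had been seen. 12 clusters with 5435 cells stayed unnamed, mostly cells with early erythroid genes. Mesenchyme means stromal-like, osteolineage-like, chondrocyte-like and fibroblast-like cells together.

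Counts were summed per library and class, and classes with at least 20 cells in every library were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, and the quasi-likelihood test with batch and genotype as terms, which leaves 1 residual degree of freedom, moderated across genes. The Benjamini-Hochberg threshold was 0.05. The moderation carried 9.79 prior degrees of freedom in mesenchyme and 28.4 in osteolineage-like cells, and in endothelial-like cells the estimate was infinite, so that all endothelial genes of like abundance shared 1 spread and their small p-values rest on that. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the same fit. Lists with under 5 tested members were left out. The estimate and its p-values rest on the 1 residual degree of freedom, so this version could hardly call any list. Its adjusted p-values therefore do not decide whether a list changed, and the preset correlation stays unchecked. Shares of cells carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, and genotypes were compared by an exact two-sided permutation test over 6 splits of the 4 libraries, whose smallest possible p is 0.333. To compare detection across depths, each cell was thinned to 1000 UMIs, a depth that all kept cells reach. The erythroid-like cells of the same library served as a class that should lack stromal genes. Barcodes of 10 to 100 UMIs served as a sample of free RNA in the droplets.

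The tests, lists, fixed genes and cell filter were chosen before the data were examined. Genes named in the text follow a rule: in each tested class, the 10 higher and 10 lower genes with the smallest p among those past the threshold, with the same direction in both batches and at least 20 CPM in the higher genotype, leaving out predicted, hemoglobin, immunoglobulin, mitochondrial, ribosomal protein, X-inactivation and Y-linked genes; 12 fixed genes; and up to 4 members of each fixed list by smallest p. The 23 lists covered niche factors, stromal identity, osteogenic, adipogenic and chondrogenic genes, m6A machinery, the KLF family, immediate early genes, interferon-stimulated genes, proliferation, p53 targets, Wnt, BMP and TGF-β and Notch response genes, matrix collagens, the unfolded protein response, glycolysis and hypoxia, sinusoidal and arterial endothelial genes, antigen presentation, and hemoglobin, neutrophil and lymphoid genes. The lymphoid list had under 5 tested members in each class and was not tested.

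The edgeR steps were checked on counts simulated from the real means and library sizes, with 200 genes changed. In mesenchyme (14272 genes), 58% of genes changed 2-fold and 100% of those changed 4-fold were recovered, and 10.2% of the calls were false. In osteolineage-like cells (13117 genes) the figures were 67%, 100% and 7.22%, and in endothelial-like cells (10691 genes) 56%, 98% and 4.94%. The share of false calls lay above the nominal 5% in mesenchyme and osteolineage-like cells, but a single draw per class does not measure the rate. The changed genes were drawn from those with a mean of at least 20 CPM, so recovery of rarer genes was not checked.

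Alternatives were a fit with no batch term, DESeq2 1.42.0 in place of edgeR and its low-count filter, RLE scaling, no low-count filter, each library left out in turn together with the batch term, other thresholds on UMIs, genes and mitochondrial share, doublets kept, Leiden resolutions 2 and 0.5, cells thinned before clustering, another denominator for shares, and the estimated correlation for lists. A fit without 1 library assumes that the lone library of that genotype varies like those of the other, and it filters genes anew, so a call lost there cannot be put down to the library alone. Added after the data had been seen were clustering without the lineage genes, tests without genes abundant in blood cells, shares of mesenchyme, and tests of whether changes differ between mesenchyme or osteolineage-like cells and endothelial-like cells. The last replaced planned tests on stromal-like cells, which numbered under 20 in each mutant library. Chondrocyte-like and fibroblast-like cells were also under 20 in at least 1 library, and no cluster was named mural, so these classes were not tested alone.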

Results

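Single-cell RNA profiles of sorted non-hematopoietic limb marrow cells were collected from control mice and from Prx1-cre;Mettl3-fl/fl mice, in which the m6A writer gene Mettl3 is floxed and the recombinase is active in limb mesenchyme. The series title places the work in the study of how the marrow niche for hematopoietic stem cells forms, and the comparison between genotypes asks which niche cells and niche genes differ at postnatal day 12. There were 2 control and 2 mutant libraries, 1 of each genotype in each processing batch. The files held 116863081 UMIs for control 1, 114143361 for control 2, 47390414 for mutant 1 and 81890483 for mutant 2. After filtering and removal of doublets, 5538, 3529, 2573 and 4419 cells remained in that order, with a median of 14610, 23800, 16320 and 10210 UMIs per cell. Although the sort excluded CD45 and Ter119, erythroid-like cells made up 6.1% of kept cells in control 1, 41.7% in control 2, 1.79% in mutant 1 and 12.7% in mutant 2, and neutrophil-like cells 0.325%, 1.05%, 7.42% and 16.7%. Unnamed cells made up 64.6%, 33.3%, 2.84% and 13.8%, mostly in clusters with some erythroid markers. The erythroid-like share therefore depends on the naming rule: control 1 had 338 erythroid-like cells here and 799 to 2493 under the other cell filters and clusterings.

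Mettl3 itself (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, minus strand of mm10) was measured at 10.3 CPM in the mesenchyme of control 1 and 10.6 CPM in control 2, against 4.99 CPM in mutant 1 and 7.06 CPM in mutant 2. The log2 difference of -0.84 ± 0.34 (SE, 2 libraries per genotype) did not pass the edgeR test with Benjamini-Hochberg adjustment (adjusted p = 0.107), and these levels rest on 143, 25, 171 and 194 UMIs for control 1, control 2, mutant 1 and mutant 2. Osteolineage-like cells held 7.81 and 9.85 CPM in controls and 4.26 and 5.91 CPM in mutants (adjusted p = 0.146). Endothelial-like cells, which are not mesenchyme, held 29.4 and 19.5 CPM in controls and 14.0 and 18.5 CPM in mutants (adjusted p = 0.999). The 3′ tags counted here may lie outside the deleted part of the gene, so these levels may check nothing about the deletion.

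The stromal-like cells, the population marked by Lepr, Cxcl12 and Adipoq that supplies niche factors, were nearly missing from the mutant mesenchyme, and osteolineage-like cells made up most of it instead. Stromal-like cells made up 75.4% of mesenchymal cells in control 1 (95% interval 73.0 to 77.7, 993 of 1317 cells) and 42.5% in control 2 (33.5 to 51.9, 51 of 120 cells). In mutant 1 they made up 0.323% (0.130 to 0.664, 7 of 2169 cells) and in mutant 2 0.601% (0.275 to 1.14, 9 of 1498 cells). Osteolineage-like cells made up 21.4% and 40.0% of control mesenchyme and 96.8% and 94.9% of mutant mesenchyme. Ibsp and Sp7 were detected markers in all of their clusters, while Bglap and Col1a1 were not detected in all. Chondrocyte-like cells made up 1.75% and 15.8% in controls and 1.29% and 4.47% in mutants.

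Over all named non-hematopoietic cells, stromal-like cells differed by -39.5 percentage points between mutant and control means, with -71.9 points in batch 1 and -7.14 points in batch 2. Leaving out control 1 gave -7.17 points and leaving out control 2 gave -71.8 points. Osteolineage-like cells differed by 62.4 points, with 73.0 and 51.8 points in the 2 batches. Each of these had an exact permutation p of 0.333, the smallest that 2 libraries against 2 allow. Endothelial-like cells differed by -21.7 points (exact permutation p = 0.667), and the sign turned to 17.8 points without control 2, so no direction is reported. Because Cxcl12, Adipoq and Lpl lead the stromal-like cluster, the cells were also clustered without the lineage genes, and 994, 49, 6 and 9 stromal-like cells were then found in control 1, control 2, mutant 1 and mutant 2. One cluster counted as osteolineage-like is led by Ccn2, Omd and Olfml2b. It held 47 cells of control 1, 0 of control 2, 648 of mutant 1 and 6 of mutant 2. Counting it as stromal-like would give 79.0%, 42.5%, 30.2% and 1.0% of mesenchyme in control 1, control 2, mutant 1 and mutant 2. A further osteolineage-like cluster, led by Col12a1 and Tnn, shares the leading genes Col12a1, Tnc and Olfml2b with the Ccn2 cluster. It held 2 cells of control 1, 6 of control 2, 10 of mutant 1 and 291 of mutant 2. Shares with both clusters moved were not computed, so the 1.0% in mutant 2 does not bound the effect of this naming choice. The sort and the unequal yield of mesenchymal cells can set such shares.

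**Figure D1:**
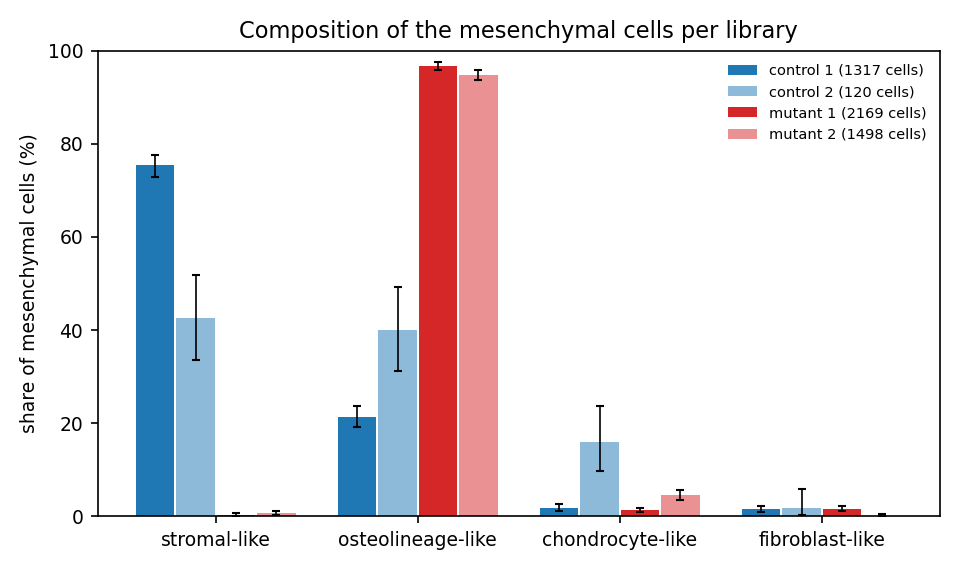
Share of mesenchymal cells (percent, vertical axis from 0) assigned to 4 classes in each of the 4 libraries; bars are single libraries, controls in blue and mutants in red, and error bars are exact 95% binomial intervals. Stromal-like cells reach 75.4% and 42.5% in the controls and 0.323% and 0.601% in the mutants.

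Across the whole mesenchyme most tested genes of the hematopoietic niche fell steeply in mutant libraries. Cxcl12, the chemokine that retains stem cells in marrow (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), fell by 5.23 on the log2 scale (SE 0.39, adjusted p = 1.42e-05), from 9357 and 2890 CPM in controls to 150 and 128 CPM in mutants. Kitl, which encodes stem cell factor (ENSMUSG00000019966, chromosome 10, 100015630 to 100100416), fell by 4.58 (SE 0.35, adjusted p = 1.42e-05). Il7, a growth factor of lymphoid progenitors, fell by 6.87 (SE 0.43, adjusted p = 5.25e-06), Igf1 fell by 5.69 (SE 0.26, adjusted p = 8.80e-07), and Angpt1, a ligand of the receptor Tek, fell by 2.29 (SE 0.29, adjusted p = 4.32e-04). Csf1, the macrophage and osteoclast growth factor, went the other way and rose by 1.26 (SE 0.21, adjusted p = 0.00225). Of 13 tested niche factors, 10 fell, 2 rose and 1 did not pass, with 11 lower and 2 higher when adjusted over the list alone; camera gave adjusted p = 2.79e-18 for the list. With an estimated correlation, which could hardly call any list here, camera gave adjusted p = 0.555. Cxcl12, Kitl, Il7, Igf1 and Angpt1 stayed past the threshold without any 1 library (Cxcl12 between -6.07 and -4.37), while Csf1 did not: it gave 1.93 without control 1 (adjusted p = 0.0996), 0.80 without control 2 (adjusted p = 0.345) and 0.57 without mutant 1 (adjusted p = 0.697).

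Several stromal identity genes fell as well. Lepr, the leptin receptor that marks these cells (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352), fell by 3.67 (SE 0.23, adjusted p = 5.40e-06), and the transcription factor genes Ebf3 and Ebf2 fell by 3.96 and fell by 4.69. Of 16 list members 9 fell, 2 rose and 5 did not pass, with 11 lower and 2 higher when adjusted over the list alone (camera adjusted p = 7.32e-09, but adjusted p = 0.555 with an estimated correlation). Adipogenic genes moved with them: Adipoq, which encodes adiponectin, fell by 7.05 (SE 0.44, adjusted p = 5.40e-06), Lpl fell by 6.05, Apoe fell by 5.31, and Pparg, the central adipogenic regulator, fell by 3.64. On the adipogenic list 10 of 15 members fell, 2 rose and 3 did not pass, with 12 lower and 2 higher when adjusted over the list alone (camera adjusted p = 2.79e-18, and adjusted p = 0.555 with an estimated correlation). The 10 lower genes with the smallest p included Kng2 (-7.50), the BMP antagonist gene Chrdl1 (-7.21) and the retinoic acid synthesis gene Aldh1a2 (-7.40). Without control 1, Lepr stood at -2.54 and no longer passed (adjusted p = 0.0708), while Ebf3, Ebf2, Adipoq, Lpl, Apoe and Pparg passed without any 1 library.

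Many bone genes moved the opposite way. Mepe, Dmp1 and Ibsp, genes of mineralizing bone cells, rose by 3.74 (SE 0.29, adjusted p = 1.42e-05), 2.08 (SE 0.25, adjusted p = 2.50e-04) and 2.47 (SE 0.28, adjusted p = 2.05e-04), and the osteoblast transcription factor gene Sp7 rose by 1.20 (adjusted p = 0.00281). Runx2 stood at 0.21 (adjusted p = 0.527). Bglap, which encodes osteocalcin, fell by 1.41 (SE 0.29, adjusted p = 0.00606) although its cell class held a larger share. On the osteogenic list 13 of 25 members rose, 2 fell and 10 did not pass, with 14 higher and 2 lower when adjusted over the list alone (camera adjusted p = 3.83e-05, and adjusted p = 0.555 with an estimated correlation). Scx, a tendon and entheseal regulator, and the cell cycle gene Ccnd1 rose by 3.34 and 2.96. Several of these calls did not pass in the fits without 1 library, which also lack the batch term. Without control 1, Ibsp gave 2.63 (adjusted p = 0.0864), Dmp1 1.80 (adjusted p = 0.0574), Sp7 1.07 (adjusted p = 0.124) and Bglap -2.06 (adjusted p = 0.0814). Without control 2, Ibsp gave 2.40 (adjusted p = 0.0560) and Bglap -0.68 (adjusted p = 0.393). Without mutant 1, Sp7 gave 1.36 (adjusted p = 0.0881) and Bglap -1.31 (adjusted p = 0.228), and without mutant 2, Sp7 gave 0.99 (adjusted p = 0.176).

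**Figure D2:**
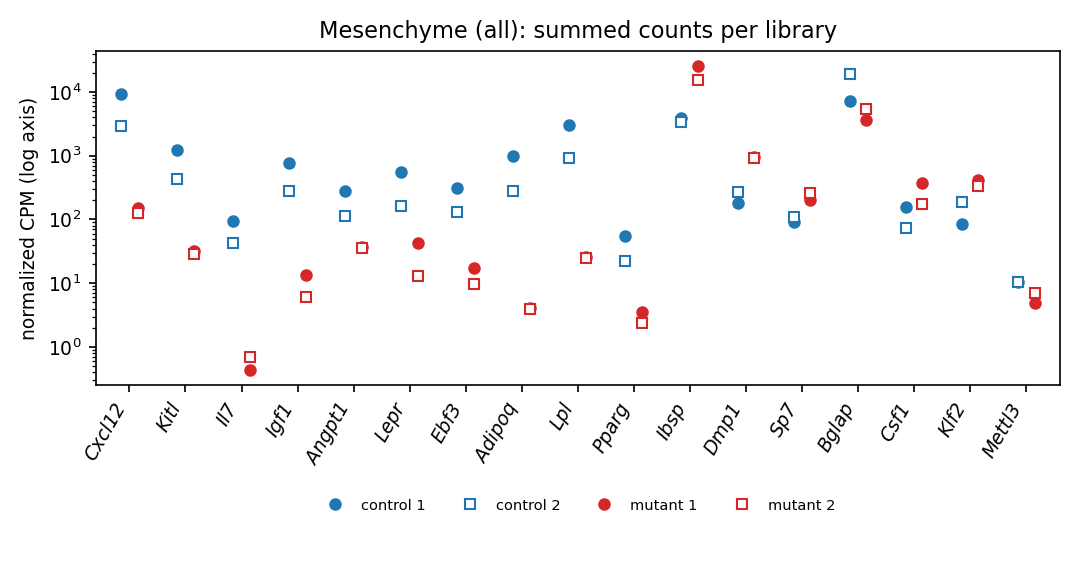
Normalized CPM (vertical, log axis) of niche, adipogenic, bone and fixed genes in the summed mesenchyme of each library; circles are replicate 1, squares replicate 2, controls blue and mutants red. Cxcl12 lies at 9357 and 2890 CPM in controls and 150 and 128 CPM in mutants, while Ibsp is higher in both mutants.

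At matched depth, fewer mesenchymal cells of the mutants held a Cxcl12 UMI. Cxcl12 is a marker of the stromal-like class, so this largely follows the share of that class and is not separate support. With every cell thinned to 1000 UMIs, a Cxcl12 UMI was found in 77.9% of mesenchymal cells of control 1 (75.6 to 80.1) and 42.5% of control 2 (33.5 to 51.9), against 8.11% of mutant 1 (7.0 to 9.34) and 6.08% of mutant 2 (4.92 to 7.41). Unthinned shares were 84.5%, 50%, 21.9% and 17.6%. In erythroid-like cells of the same libraries the thinned shares were 4.14%, 0%, 0% and 0%. The median depths of mesenchymal cells were 6546, 10390, 18400 and 15850 UMIs for control 1, control 2, mutant 1 and mutant 2, and those of erythroid-like cells 8014, 25010, 10030 and 18190 UMIs. The 7 and 9 stromal-like cells left in the mutant libraries were too few to test. In them Cxcl12 stood at 8042 and 8616 CPM against 21210 and 17790 CPM in control stromal-like cells, Kitl at 966 and 1577 CPM against 2780 and 2622 CPM, and Lepr at 187 and 133 CPM against 1242 and 955 CPM. Csf1 was higher in them, at 717 and 515 CPM against 319 and 375 CPM, and Angpt1 stood at 249 and 664 CPM against 609 and 672 CPM.

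Klf2, a transcription factor gene fixed for naming (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), rose in mutant mesenchyme by 1.59 (SE 0.32, adjusted p = 0.00606), by 2.32 in batch 1 and 0.84 in batch 2. Thinned cells held a Klf2 UMI in 4.63% and 10.8% of control and 24.5% and 23% of mutant mesenchymal cells, against 0.296%, 0.136%, 2.17% and 0.178% of erythroid-like cells in control 1, control 2, mutant 1 and mutant 2. In stromal-like cells, untested, Klf2 stood at 39.8 and 55.1 CPM in controls and 249 and 199 CPM in mutants, the latter from 16 and 12 UMIs. Osteolineage-like cells held 116 and 257 CPM in controls and 343 and 324 CPM in mutants. Control osteolineage-like cells thus held more Klf2 than control stromal-like cells. The larger osteolineage-like share in mutants would by itself raise Klf2 in the mesenchyme sum and in the thinned shares. How much it adds to the Klf2 change was not measured. The Klf2 call in mesenchyme did not pass without control 1 (1.0, adjusted p = 0.140), without mutant 1 (1.29, adjusted p = 0.219) or without mutant 2 (1.61, adjusted p = 0.0672). On the KLF list 3 of 14 members rose, none fell and 11 did not pass, with 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.521). On the m6A machinery list 4 of 20 members rose and 16 did not pass, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0932). They include the reader gene Ythdf2 (1.60) and the writer complex gene Rbm15 (1.26). Without control 1, Ythdf2 gave 1.45 (adjusted p = 0.0556) and Rbm15 0.80 (adjusted p = 0.167). Without mutant 1 they gave 1.47 (adjusted p = 0.0699) and 0.98 (adjusted p = 0.335), and without mutant 2 Rbm15 gave 1.36 (adjusted p = 0.0976).

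Immune and matrix genes formed further groups in mesenchyme, in sums that mix the loss of stromal-like cells with change within classes. Interferon-stimulated genes fell in 15 of 22 tested members with 7 not passing, and in 17 when adjusted over the list alone (camera adjusted p = 1.03e-07, but adjusted p = 0.604 with an estimated correlation), among them Parp14 (-3.62) and Rsad2 (-4.45). Antigen presentation genes fell in 10 of 13 and all 13 when adjusted over the list alone (camera adjusted p = 7.32e-09, and adjusted p = 0.555 with an estimated correlation), with H2-K1 at -1.93 and H2-T23 at -2.86. Chondrogenic genes, which build cartilage, fell in 7 of 15, and in 8 when adjusted over the list alone (camera adjusted p = 5.81e-07, adjusted p = 0.555 with an estimated correlation). Acan stood at -3.86 and Col10a1 at -3.24. Chondrocyte-like cells made up 15.8% of mesenchyme in control 2 (19 cells), 1.75% in control 1, 1.29% in mutant 1 and 4.47% in mutant 2. The chondrogenic sums therefore also mix in the share of that class. Without control 2 the chondrogenic list's median turned from -1.08 to 0.11 and the list did not pass (adjusted p = 0.348), Col10a1 gave -1.44 (adjusted p = 0.258) and Acan -2.21. Without mutant 1 Acan gave -3.78 (adjusted p = 0.0806) and Col10a1 -2.82 (adjusted p = 0.152), and without mutant 2 Col10a1 gave -4.96. H2-K1 gave -2.07 without mutant 1 (adjusted p = 0.0543), and without control 1 Parp14 gave -2.74 (adjusted p = 0.0655) and Rsad2 -3.77 (adjusted p = 0.0757).

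Matrix collagen genes fell in 10 of 23 members and rose in 3, with 10 lower and 6 higher when adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.555 with an estimated correlation). The list held Col6a1 at -1.97 and the fibrillin gene Fbn1 at -1.93. Without control 1 the collagen list did not pass (adjusted p = 0.0763) and neither did it without mutant 2 (adjusted p = 0.248). Fbn1 gave -1.0 (adjusted p = 0.222) and -1.64 (adjusted p = 0.136) in those fits, and -2.68 without mutant 1 (adjusted p = 0.0542).

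Smaller groups were mixed. Notch response genes fell in 3 of 10 members, 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.767 with an estimated correlation), led by Heyl at -2.67. The list did not pass without control 1 (adjusted p = 0.383) or without mutant 2 (adjusted p = 0.0516), and Heyl gave -1.62 without control 1 (adjusted p = 0.0987). Proliferation genes rose in 5 of 20, 6 when adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.767 with an estimated correlation), with Cdc20 at 1.68. The list's median turned to -0.10 without control 1 and Cdc20 gave 1.57 there (adjusted p = 0.0620) and 1.55 without mutant 1 (adjusted p = 0.0956). Arterial endothelial genes fell in 3 of 9, and 3 when adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.555 with an estimated correlation). Among them was the elastic fibre gene Fbln5 at -3.17. Without control 1 the list gave adjusted p = 0.0763 and Fbln5 -2.17 (adjusted p = 0.0627).

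Further lists did not pass camera in mesenchyme, among them p53 targets (4 of 18 rose, adjusted p = 0.101), Wnt response genes (4 of 15 rose and 4 fell, adjusted p = 0.521) and BMP and TGF-β response genes (7 of 17 rose and 3 fell, adjusted p = 0.174). The others were the unfolded protein response (3 of 16 rose, adjusted p = 0.101), immediate early genes (2 of 20 rose and 3 fell, adjusted p = 0.101), glycolysis and hypoxia genes (2 of 17 rose and 3 fell, adjusted p = 0.898) and sinusoidal endothelial genes (1 of 10 fell, adjusted p = 0.272). When adjusted over the list alone the p53 list had 4 higher, Wnt 5 higher and 4 lower, and BMP and TGF-β 9 higher and 3 lower. The unfolded protein response had 3 higher, immediate early genes 2 higher and 3 lower, glycolysis 2 higher and 4 lower, and sinusoidal genes 1 lower when adjusted over the list alone. The 2 higher immediate early genes were the heat-shock genes Hspa1a and Hspa1b, held on that list as genes of dissociation stress. They rose by 2.66 (SE 0.24, adjusted p = 3.44e-05) and 2.57 (SE 0.25, adjusted p = 6.10e-05) and passed without any 1 library. For the Wnt, BMP and TGF-β, and glycolysis lists the median was above 0 and the mean below 0.

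Transcripts of blood cells moved with genotype in the same mesenchymal cells. Hemoglobin and erythroid genes were lower in 6 of 11 tested members, also 6 when adjusted over the list alone (camera adjusted p = 5.05e-06, adjusted p = 0.555 with an estimated correlation). That list did not pass without mutant 1 (adjusted p = 0.0941), and its median ran from -4.50 without mutant 2 to -0.72 without mutant 1. Neutrophil genes were higher in 7 of 8 and lower in 1, the same counts when adjusted over the list alone (camera adjusted p = 4.98e-15, adjusted p = 0.555 with an estimated correlation), and S100a9 stood at 1.37 and 5.95 CPM in controls and 63.5 and 525 CPM in mutants. Its log2 change was 5.98, and 5.63 without control 1 (adjusted p = 0.0970). Of the 10 higher genes with the smallest p in mesenchyme, 5 were transcripts abundant in blood cells (S100a9, Cstdc5, Lcn2, Stfa2 and Cstdc4), with a mean of 2284 CPM (Lcn2) to 40880 CPM (S100a9) there. The others were Slpi, Mepe, Scx, S100a4 and Ccnd1. Without control 1, Cstdc5 (adjusted p = 0.154), Stfa2 (adjusted p = 0.223), Cstdc4 (adjusted p = 0.163) and Slpi (adjusted p = 0.0633) did not pass. Without control 2, Stfa2 (adjusted p = 0.0611) and Cstdc4 (adjusted p = 0.0526) did not.

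In mesenchyme 2838 of the 2839 called genes had the same direction in both batches. The test itself favours genes whose within-batch differences agree, so such agreement, here and in the classes below, is not separate support. In total 1377 genes rose and 1462 fell among 14272 tested. The count was 389 without control 1, 436 without mutant 1 (118 higher and 318 lower), 864 without mutant 2 and 1641 without control 2 (605 higher and 1036 lower). It was 1001 with all 4 libraries and no batch term, which the fits without 1 library lack as well. These sums mix the loss of stromal-like cells with change within classes. In osteolineage-like cells alone, interferon-stimulated genes had 1 of 16 members higher and 1 lower (camera adjusted p = 0.300). Stromal identity genes had 1 of 13 higher (camera adjusted p = 0.369) and adipogenic genes 2 of 11 higher and 1 lower (0.428). Proliferation genes had 1 of 20 higher and 1 lower (0.436). The antigen presentation, matrix collagen, hemoglobin and neutrophil lists passed in both.

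Within osteolineage-like cells, the bone-forming class that was compared alone, the mutants had less transcript of Bglap, the osteocalcin gene, and of Col1a1, and more of Csf1. Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464, minus strand) fell by 2.66 (SE 0.20, adjusted p = 1.26e-10), from 17950 and 33980 CPM to 3138 and 4894 CPM, and its neighbour Bglap2 fell by 2.43 (adjusted p = 8.56e-10). Col1a1, which encodes a chain of type I collagen, fell by 1.30 (SE 0.19, adjusted p = 9.56e-06). Csf1 (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469, minus strand) rose by 3.01 (SE 0.25, adjusted p = 6.64e-10), from 43.8 and 15.9 CPM to 323 and 148 CPM. Runx2 and Sp7, the osteoblast transcription factor genes, stood at -0.18 (adjusted p = 0.641) and 0.08 (adjusted p = 0.861). Without control 1 the values were -3.07 for Bglap (adjusted p = 0.0768), -2.91 for Bglap2 (adjusted p = 0.0731), -1.16 for Col1a1 (adjusted p = 0.365) and 3.90 for Csf1 (adjusted p = 0.0731). Without control 2 they were -2.16 (adjusted p = 0.114), -1.88 (adjusted p = 0.117), -1.41 (adjusted p = 0.244) and 2.43 (adjusted p = 0.121). Col1a1 did not pass without mutant 1 (-1.16, adjusted p = 0.478) or mutant 2 (-1.41, adjusted p = 0.228) either.

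The 2 batches filled this class largely from different clusters. Cluster 0, led by Bglap and Ifitm5, held 216 of 282 cells in control 1 and 1142 of 2099 in mutant 1. Cluster 5, led by Bglap and Bglap2, held 36 of 48 cells in control 2 and 922 of 1421 in mutant 2. The cluster led by Ccn2, Omd and Olfml2b has Csf1 among its 10 leading genes. It held 47 of 282 cells in control 1 and 648 of 2099 in mutant 1. A cluster led by Mepe and Dmp1 held 16 of 282 cells in control 1 and 299 of 2099 in mutant 1. For control 2 and mutant 2 the Mepe cluster held 6 of 48 and 197 of 1421 cells. Another, led by Col12a1 and Tnn, held 6 of 48 cells in control 2 and 291 of 1421 in mutant 2. In batch 2 the Ccn2 cluster held 0 control and 6 mutant cells, and Csf1 stood at 15.9 CPM in control 2 and 148 CPM in mutant 2. The Col12a1 and Tnn cluster shares the leading genes Col12a1, Tnc and Olfml2b with the Ccn2 cluster. It held 6 of 48 cells of control 2 and 291 of 1421 of mutant 2, shares that differed far less than Csf1 did. How much the mix of clusters adds to the Csf1 change was not measured. The change of Csf1 within clusters was not tested.

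Several other matrix genes fell too, while a few rose. Dcn and Lum, small proteoglycan genes, fell by 2.58 (SE 0.22, adjusted p = 1.48e-09) and fell by 2.13 (SE 0.22, adjusted p = 2.01e-08). The list of matrix collagens and related genes had 11 of 22 members lower, 3 higher and 8 not passing, with 11 lower and 4 higher when adjusted over the list alone (camera adjusted p = 4.48e-05, adjusted p = 0.732 with an estimated correlation). On the osteogenic list 6 of 25 fell and 5 rose, with 9 lower and 6 higher when adjusted over the list alone (camera adjusted p = 0.122). Col11a2, a minor fibrillar collagen gene, fell by 3.85, the growth factor gene Ptn fell by 3.26 and the galanin gene Gal fell by 4.36. Without control 1, Dcn gave -2.47 (adjusted p = 0.0731), Lum -2.04 (adjusted p = 0.0731) and Gal -3.33 (adjusted p = 0.0535). Without control 2, Dcn gave -2.59 (adjusted p = 0.0802), Lum -2.20 (adjusted p = 0.0667) and Ptn -2.93 (adjusted p = 0.0649). Col11a2 gave -3.58 (adjusted p = 0.0561) and -3.97 (adjusted p = 0.0529) in these fits.

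Some m6A machinery genes, p53 targets and BMP and TGF-β response genes rose in osteolineage-like cells, although most members of the first 2 lists did not pass. On the m6A list 6 of 20 members rose and 14 did not pass, with 9 higher when adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.732 with an estimated correlation), among them the reader gene Ythdf2 (1.88, SE 0.24, adjusted p = 9.58e-07) and Rbm15 (1.60). The p53 list had 6 of 18 members higher and 12 not passing, also 6 when adjusted over the list alone (camera adjusted p = 0.00285, adjusted p = 0.732 with an estimated correlation), with Phlda3 at 1.86. The BMP and TGF-β list had 7 of 17 members higher, 2 lower and 8 not passing, with 8 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.732 with an estimated correlation), among them the ligand gene Bmp2 (1.52) and the antagonist gene Nog (2.13). Without control 1, Ythdf2 gave 2.01 (adjusted p = 0.0731), Rbm15 1.30 (adjusted p = 0.134), Phlda3 2.56 (adjusted p = 0.0561), Bmp2 1.43 (adjusted p = 0.101) and Nog 2.80 (adjusted p = 0.0958). Without control 2 they gave 1.78 (adjusted p = 0.0810), 1.80 (adjusted p = 0.0896), 1.36 (adjusted p = 0.104), 1.58 (adjusted p = 0.0892) and 1.98 (adjusted p = 0.0961).

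Antigen presentation genes fell in 7 of 10 members, also 7 when adjusted over the list alone (camera adjusted p = 1.40e-05, adjusted p = 0.732 with an estimated correlation). The class I genes H2-K1 and H2-T23 stood at -1.44 and -2.57. They gave -1.14 (adjusted p = 0.0978) and -2.82 (adjusted p = 0.0690) without control 1, and -1.71 (adjusted p = 0.0674) and -2.38 (adjusted p = 0.0703) without control 2.

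Niche factors did not move one way within osteolineage-like cells. On that list 3 of 11 rose (Csf1, Bmp4 and Angpt1), 2 fell (Ptn and Igf1) and 6 did not pass, with 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.857). The list's median was above 0 and its mean below. Cxcl12 stood at 0.76 (adjusted p = 0.204), with -0.52 in batch 1 and 2.83 in batch 2, and Kitl at 0.09 (adjusted p = 0.875). Both turned negative without control 2, to -0.63 and -0.42. Bmp4 rose by 2.12, and gave 3.86 without control 1 (adjusted p = 0.0561) and 1.49 without control 2 (adjusted p = 0.107). Igf1 stood at -3.41, and at -1.37 without control 1 (adjusted p = 0.262). Angpt1 stood at 0.99, and gave 2.04 (adjusted p = 0.0765), 0.48 (adjusted p = 0.327), 0.91 (adjusted p = 0.195) and 0.99 (adjusted p = 0.0674) without control 1, control 2, mutant 1 and mutant 2. Csf1 gave 3.90 without control 1 (adjusted p = 0.0731) and 2.43 without control 2 (adjusted p = 0.121), and Ptn -2.93 without control 2 (adjusted p = 0.0649).

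Klf2 stood at 0.86 in osteolineage-like cells (SE 0.25, adjusted p = 0.0164), with 1.46 in batch 1 and 0.23 in batch 2. It passed in none of the 4 fits that leave out 1 library, with 0.40 (adjusted p = 0.526), 1.33 (adjusted p = 0.126), 0.64 (adjusted p = 0.540) and 0.94 (adjusted p = 0.137) without control 1, control 2, mutant 1 and mutant 2. The unfolded protein response list had 3 of 16 higher and 2 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.702). Of the immediate early genes 3 of 20 rose and 1 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.857). Hspa1a and Hspa1b rose by 1.79 and 1.95. They gave 1.93 (adjusted p = 0.0808) and 2.45 (adjusted p = 0.0561) without control 1, and 1.68 (adjusted p = 0.102) and 1.64 (adjusted p = 0.0825) without control 2.

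**Figure D3:**
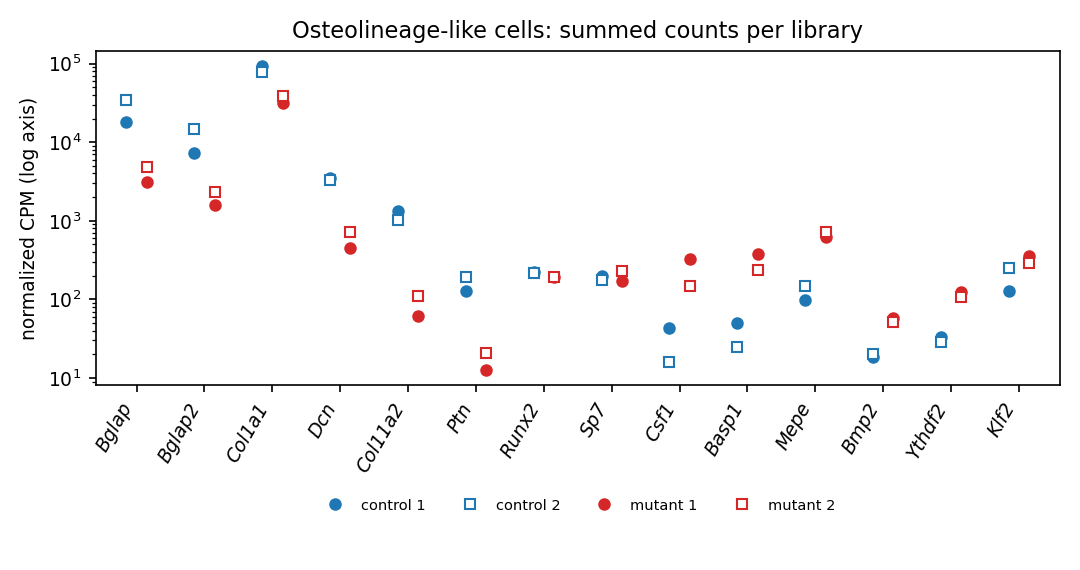
Normalized CPM (vertical, log axis) of matrix, signal, m6A and fixed genes in the summed osteolineage-like cells of each library; circles are replicate 1, squares replicate 2, controls blue and mutants red. Bglap lies at 17950 and 33980 CPM in controls and 3138 and 4894 CPM in mutants, and Csf1 at 43.8 and 15.9 against 323 and 148 CPM.

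In total 1285 genes rose and 882 fell among 13117 tested in osteolineage-like cells, 2152 of the 2167 with the same direction in both batches. Control 2 gave 48 of these cells. The count of calls was 12 (0 higher and 12 lower) without control 1, 25 (4 higher and 21 lower) without control 2, 590 without mutant 1 and 1151 without mutant 2, and 922 by DESeq2 with no low-count filter. Of 86 named genes past the threshold, 3 stayed past it without control 1 and 9 without control 2. Hemoglobin genes were lower in 11 of 11 members and 11 when adjusted over the list alone (camera adjusted p = 2.24e-14), and neutrophil genes higher in 7 of 9 and 7 when adjusted over the list alone (camera adjusted p = 1.42e-10), both at adjusted p = 0.732 with an estimated correlation. S100a9 stood at 1.42 and 3.79 CPM in controls and 54.7 and 445 CPM in mutants, a change of 6.05 that was 6.05 without control 1 (adjusted p = 0.148) and 7.46 without control 2 (adjusted p = 0.129). Of the 10 higher genes with the smallest p, 4 were transcripts abundant in blood cells (S100a9, Cstdc5, Stfa1 and Lcn2).

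Endothelial-like cells, which do not belong to the mesenchyme, served as the contrast, and in them most tested genes of sinusoidal vessels fell. Stab2, a scavenger receptor of sinusoidal endothelium, fell by 2.15 (SE 0.20, adjusted p = 3.06e-24), Ctsl fell by 2.30 (SE 0.19, adjusted p = 4.51e-32), the cytokine receptor gene Il6st fell by 1.65 and Lrg1 fell by 1.36. Of 12 sinusoidal genes 9 fell, 1 rose and 2 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 2.27e-10, adjusted p = 0.692 with an estimated correlation). Genes of lipid uptake and handling fell too: Fabp4, from 14370 and 12580 CPM to 3732 and 4115 CPM, fell by 1.78 (SE 0.19, adjusted p = 6.17e-19), and Lpl fell by 2.19 and Pparg fell by 1.49. The adipogenic list had 6 of 9 members lower and 7 when adjusted over the list alone (camera adjusted p = 4.55e-09, adjusted p = 0.692 with an estimated correlation). Control 2 held 551 of these cells and control 1 held 29. With doublets kept, 7 of the 558 calls in this class remained, although 544 of the 547 with a value kept their sign. With no batch term 102 remained. Without control 2, Stab2 gave -1.95 (adjusted p = 0.682), Ctsl -2.22 (adjusted p = 0.147), Il6st -1.63 (adjusted p = 0.625) and Lrg1 -1.54 (adjusted p = 0.342). Fabp4 gave -1.90 (adjusted p = 0.174), Lpl -1.64 (adjusted p = 0.910) and Pparg -1.43 (adjusted p = 0.910) in that fit, and without mutant 2 Lpl gave -3.42 and Pparg -2.36.

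The 2 genotypes filled this class from different clusters. Most control cells lay in a cluster led by Fabp4, Stab2 and Adamts5, and most mutant cells in a cluster led by Flt1 and Aplnr. Stab2, Fabp4, Lrg1, Clca3a1 and Tfpi are among the leading genes of the first, and their change within clusters was not tested.

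The lower genes with the smallest p also included Fgf23, the phosphate hormone gene (-4.46, SE 0.29, adjusted p = 1.29e-48), the atypical chemokine receptor gene Ackr1 (-2.79) and Clca3a1 (-3.06). Fgf23 was the 1 gene that passed without control 2 (-4.53, adjusted p = 0.0325), where Ackr1 gave -2.91 (adjusted p = 0.147) and Clca3a1 -3.10 (adjusted p = 0.325). The fibulin gene Fbln2 rose by 2.66, and gave 1.31 without control 2 (adjusted p = 0.910). The adhesion molecule gene Vcam1 fell by 1.92, and gave -1.96 without control 2 (adjusted p = 0.368).

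As a list, niche factors did not pass in endothelial-like cells (camera adjusted p = 0.106). Among them 3 of 11 fell, 1 rose and 7 did not pass, with 4 lower and 1 higher when adjusted over the list alone. Kitl rose by 1.0 (SE 0.25, adjusted p = 0.00179) and Cxcl12 stood at -1.0 (SE 0.25, adjusted p = 0.00183). Cxcl12 turned to 0.25 without control 1, and gave -3.09 without control 2 (adjusted p = 0.317), -2.30 without mutant 1 (adjusted p = 1.51e-07) and -0.90 without mutant 2 (adjusted p = 0.741). Kitl gave 2.03 without control 1 (adjusted p = 1.50e-04), 0.36 without control 2 (adjusted p = 0.974), 0.43 without mutant 1 and 2.34 without mutant 2 (adjusted p = 0.00391), and the value of 0.43 did not pass.

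Arterial genes had 3 of 10 members higher, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0374, adjusted p = 0.692 with an estimated correlation). The list's median turned to -0.20 without mutant 1 and -0.77 without control 2, so no direction is reported for the arterial list. The stem cell antigen gene Ly6a stood at 1.05, and gave 0.98 without control 2 (adjusted p = 0.923), 0.74 without mutant 1 (adjusted p = 0.360) and 1.67 without mutant 2. Glycolysis and hypoxia genes had 2 of 16 lower and 4 when adjusted over the list alone (camera adjusted p = 2.59e-04, adjusted p = 0.692 with an estimated correlation), and the list did not pass without mutant 2 (adjusted p = 0.570). These were Pdk1 (-1.45) and the vascular growth factor gene Vegfa (-1.75). They gave -1.38 (adjusted p = 0.914) and -1.50 (adjusted p = 0.930) without control 2, and -1.34 (adjusted p = 0.101) and -2.09 (adjusted p = 0.161) without mutant 2. The m6A list had camera adjusted p = 0.967 and the KLF list 0.0506, and Klf2 stood at 0.54 (adjusted p = 0.118).

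Transcripts typical of bone and blood cells also moved in the endothelial-like class. On the osteogenic list 9 of 14 members were higher and 11 when adjusted over the list alone (camera adjusted p = 4.58e-09, adjusted p = 0.692 with an estimated correlation), with Spp1 at 11.7 and 11.1 CPM in controls and 259 and 392 CPM in mutants and Col1a1 at 76.4 and 17.3 against 207 and 313 CPM. Without control 2, Spp1 gave 4.78 (adjusted p = 0.174) and Col1a1 1.76 (adjusted p = 0.711). S100a9 stood at 0 and 12.2 CPM in controls and 28.0 and 516 CPM in mutants. Of the 10 higher genes with the smallest p, 4 were transcripts abundant in blood cells (S100a9, S100a8, Cstdc5 and Stfa1) and 3 were bone genes (Spp1, Col1a1 and Col1a2). Hemoglobin genes were lower in 8 of 9 and 9 when adjusted over the list alone (camera adjusted p = 1.32e-12, adjusted p = 0.692 with an estimated correlation). In total 240 genes rose and 318 fell among 10691 tested, 535 of the 558 with the same direction in both batches. The count was 1 without control 2, 281 without mutant 2, 300 without control 1 and 319 without mutant 1, 128 by DESeq2 with no low-count filter, 102 with no batch term, 197 at resolution 2 and 7 with doublets kept.

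**Figure D4:**
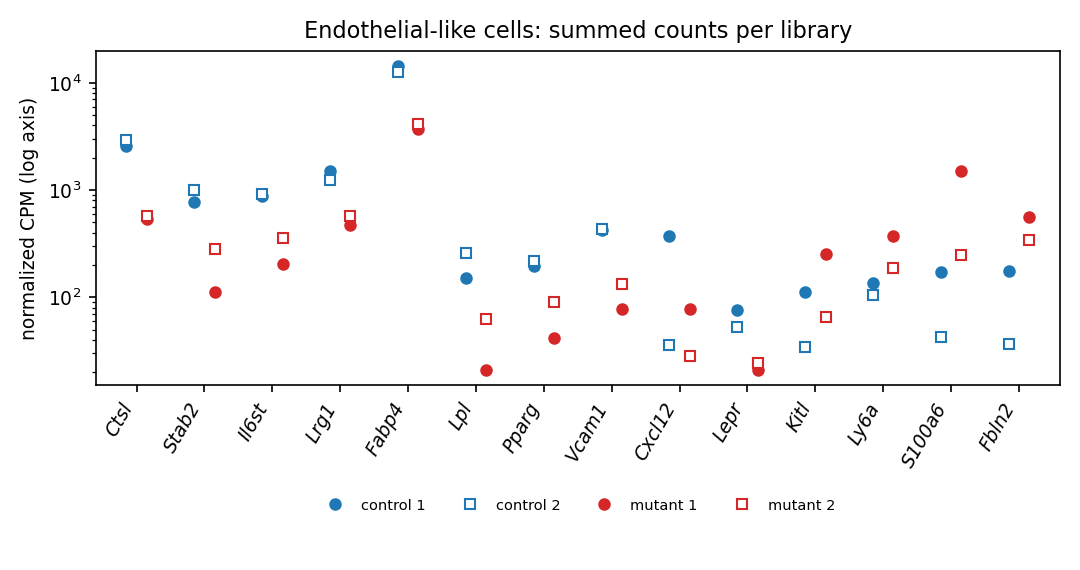
Normalized CPM (vertical, log axis) of sinusoidal, lipid, niche and vessel genes in the summed endothelial-like cells of each library; circles are replicate 1, squares replicate 2, controls blue and mutants red. Fabp4 lies at 14370 and 12580 CPM in controls and 3732 and 4115 CPM in mutants, and Lpl and Vcam1 are lower in both mutants.

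Whether the genotype effect differed between mesenchyme and endothelial-like cells was tested with an interaction term in edgeR, a test added after the data had been seen. The change in Cxcl12 was more negative in mesenchyme by -3.90 (adjusted p = 4.67e-09), that of Kitl by -5.60 (adjusted p = 4.31e-17) and that of Lepr by -2.43 (adjusted p = 2.11e-04). For Klf2 the difference was 0.83 (adjusted p = 0.40), for Csf1 1.35 (adjusted p = 0.129) and for Mettl3 -0.37 (adjusted p = 0.937), none of which passed. Of 13584 genes, 184 changed more positively and 345 more negatively in mesenchyme, and 302 genes passed without mutant 1. The Lepr change in mesenchyme alone was -2.54 without control 1 (adjusted p = 0.0708). Between osteolineage-like and endothelial-like cells 124 and 122 of 12843 genes differed, 113 in all without control 2 and 369 without control 1.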

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

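The tests of differences between classes, and the test on the barcode list of mutant 1, were chosen only after the results had been seen. With 2 libraries per genotype, no group was large enough to look for a single library apart from the others.

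The genotype effect differed between mesenchyme and endothelial-like cells for 529 genes by an interaction term in edgeR. Among the genes fixed for naming, the mutant change was more negative in mesenchyme for Cxcl12 by -3.90 (adjusted p = 4.67e-09), Kitl by -5.60 (adjusted p = 4.31e-17), Lepr by -2.43 (adjusted p = 2.11e-04), Bglap by -3.25 (adjusted p = 1.23e-04) and Pparg by -2.05 (adjusted p = 0.00271). Bone transcripts in endothelial-like cells, weighed below, add to the Bglap difference.

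A second signal lay in barcodes of 10 to 100 UMIs, which no comparison used. In mutant 2 they held Spp1 at 14280 CPM, Col1a1 at 14660 CPM and S100a8 at 4914 CPM. Control 1 and control 2 held Spp1 at 2539 and 284 CPM, Col1a1 at 5017 and 582 CPM and S100a8 at 135 and 479 CPM. The deposited list of mutant 1 has no such barcodes, so this rests on 1 mutant library.

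The first pattern weighed is the loss of stromal and niche genes, Cxcl12, Kitl and Lepr among them, in mutant mesenchyme. The called-barcode list of mutant 1 cannot account for it, since batch 2, where both libraries hold all barcodes, had a median log2 change of -3.67 over the 8 stromal markers. Greater depth of the mutant cells would raise the share with a Cxcl12 UMI, and the unthinned shares were already lower in mutants (21.9% and 17.6% against 84.5% and 50%). Thinning to 1000 UMIs, which gave differences of 69.8 and 36.4 percentage points in the 2 batches, therefore decides nothing further. Loss of stromal cells during dissociation or sorting was not tested and stays open. The heat-shock genes Hspa1a and Hspa1b, on the list of dissociation genes, were higher in mutant mesenchyme by 2.66 and 2.57, while 3 other members were lower and the list did not pass (camera adjusted p = 0.101), so a difference in handling is not excluded. Also open are the unstated mapping of mice to libraries and the sex of the mice. An effect of the Mettl3 genotype on the formation of these cells is a hypothesis that these libraries leave possible and do not separate from those.

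The second pattern is bone and neutrophil transcripts in mutant endothelial-like cells. For 9 bone genes of mutant 2, UMIs per cell in endothelial-like over erythroid-like cells had a median log2 ratio of 0.17 (SE 0.42), as free RNA reaching all droplets alike would give. Free RNA is thus a candidate source of the bone signal taken as a set. Col5a2 at 2.89 and Mmp13 at 1.03 lay above the bound of 1 set for it, and Spp1 at 0.80 and Dmp1 at 0.75 lay nearer to that bound than to 0. For 4 neutrophil genes the median was 1.19 (SE 0.25), which passes the bound of 1 set for free RNA by less than its SE, so for these free RNA and another source cannot be told apart. A biological difference in bone genes of endothelial cells was not tested.

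The third pattern is the lower Bglap in mutant osteolineage-like cells. A different mix of clusters predicts little change within the clusters of highest Bglap, but there the log2 change was -2.02 in batch 1 and -2.37 in batch 2. Bglap2, a near-identical copy, gave -1.77 and -2.26 in the same clusters. With all libraries the log2 change was -2.66 (SE 0.20). It was -3.07 without control 1 (adjusted p = 0.0768) and -2.16 without control 2 (adjusted p = 0.114), where the call did not pass. Those fits also lack the batch term; with 4 libraries and no batch term the change was -2.69 (adjusted p = 0.0455). Control 2 gave 36 cells to these clusters, and a difference in age of the cells was not tested. Hspa1a and Hspa1b were higher here by 1.79 and 1.95, calls that did not pass without control 1 or without control 2, and the list of dissociation genes did not pass (camera adjusted p = 0.857), so a difference in dissociation stays open.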

How the results depend on the processing

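Clustering without the lineage genes, leaving out genes abundant in blood cells, shares of mesenchyme, and the differences between classes were chosen after seeing the data; the other alternatives were planned. For the named genes and the called lists, taken over the alternatives, 4089 values kept direction and side of the threshold, 762 kept direction but no longer passed, 80 came to pass and 44 changed sign. Counts of calls and class shares are outside this tally and are given below, with 2 reversals of the endothelial-like share.

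Counts of calls depended on the setting. With no batch term they fell from 2839 to 1001 in mesenchyme, from 2167 to 490 in osteolineage-like and from 558 to 102 in endothelial-like cells. DESeq2, run without the low-count filter, gave 922 in osteolineage-like and 128 in endothelial-like cells, against 2396 and 497 by edgeR without that filter. Endothelial-like cells gave 7 calls with doublets kept and 197 at resolution 2; the cause was not tested. The fits that leave out 1 library also drop the batch term and filter genes anew (6086 genes tested in endothelial-like cells without control 2, against 10691), so their counts cannot be put down to the library alone. They gave 389 (control 1) to 1641 (control 2) calls in mesenchyme, 12 (control 1) to 1151 (mutant 2) in osteolineage-like and 1 (control 2) to 319 (mutant 1) in endothelial-like cells. The 529 differences between mesenchyme and endothelial-like cells, fitted with the libraries as blocks, became 302 (without mutant 1) to 382 (without mutant 2), and the 246 between osteolineage-like and endothelial-like cells 113 (without control 2) to 369 (without control 1).

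Camera with an estimated correlation called 0 of 22, 0 of 22 and 0 of 19 lists in mesenchyme, osteolineage-like and endothelial-like cells, against 13, 7 and 6 at the preset. It had 0 lists at an unadjusted p under 0.05 in each class, with a smallest p of 0.0844, 0.113 and 0.0985 in that order. With 1 residual degree of freedom it could hardly call any list, so these counts do not decide which lists changed. The fits without 1 library gave 7 (mutant 2) to 13 (control 2) lists in osteolineage-like cells and 6 (mutant 2) to 10 (mutant 1) in endothelial-like cells, which also had 10 at most 5% mitochondrial UMIs and 10 with doublets kept.

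The 44 values that changed sign, and the ranges that hold them, follow, and the cause was not tested. The median of the chondrogenic list in mesenchyme ranged from -2.45 (without control 1) to 0.11 (without control 2). The median of the proliferation list in mesenchyme was -0.13 with doublets kept and ranged from -0.10 (without control 1) to 0.90 (without control 2). That of the arterial list in endothelial-like cells ranged from -0.77 (without control 2) to 1.79 (without control 1). In mesenchyme Ptx3 ranged from -3.27 (without mutant 1) to 0.28 (without control 1). In osteolineage-like cells Fabp4 was 1.98 at 2000 UMIs (edgeR adjusted p = 1.52e-05) and 1.73 at 500 UMIs (0.00411), and passed with the opposite sign in both. Over the left-out libraries it ranged from -4.98 (without control 2) to 0.92 (without control 1). In endothelial-like cells Cxcl12 ranged from -3.09 (without control 2) to 0.25 (without control 1) and Fbln5 from -0.44 (without control 2) to 1.90 (without control 1), and with doublets kept Hbb-bs was 0.59 and Hbb-bt 0.17.

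The other genes that changed sign had not passed with all 4 libraries at the chosen settings. Ly6a in mesenchyme ranged from -0.54 (without mutant 1) to 2.28 (without control 1). In osteolineage-like cells the ranges over the 4 left-out libraries were -0.26 to 8.28 for Adipoq, -0.63 to 2.97 for Cxcl12, -0.42 to 0.94 for Kitl, -0.85 to 0.89 for Lepr, -0.11 to 0.31 for Sp7, -0.0058 to 1.48 for Ebf1 and -1.88 to 0.19 for Mcm3. Adipoq there was -2.71 with list genes left out of clustering, where it passed, -2.08 at resolution 2, -0.68 at resolution 0.5, -1.15 with doublets kept and -0.041 with blood-cell genes left out. At resolution 2 Cxcl12 was -0.20 and Kitl -1.11. At most 5% mitochondrial UMIs gave -0.20 for Kitl, -0.093 for Pparg and -0.13 for Nr2f2. Kitl was -0.020 with no batch term, Pparg -0.012 with list genes left out of clustering, and Sp7 -0.13 at 2000 UMIs. In endothelial-like cells the ranges were -0.75 to 0.052 for Cdkn1a, -0.19 to 2.38 for Dusp1, -0.58 to 1.79 for Efnb2 and -1.89 to 0.76 for Fos, and Hspa1a was -0.0089 at resolution 2.

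The osteolineage-like share difference of 62.4 points ranged from 45.1 (without mutant 1) to 79.7 (without mutant 2). The endothelial-like difference of -21.7 points ranged from -61.2 (without control 1) to 17.8 (without control 2), and was 3.16 over all kept cells. Planned tests on stromal-like, chondrocyte-like, fibroblast-like and mural-like cells, and the differences planned for stromal-like cells, were not run because the cells were too few. Depth limits the endothelial-like comparison in batch 1, with 171133 UMIs in control 1 and 289114 in mutant 1, and the other 2 comparisons in control 2, with 2006223 mesenchyme and 1272442 osteolineage UMIs.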

Other observations

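The Y-linked gene Ddx3y, chosen after its values were seen, was lower in mutant libraries in mesenchyme (-2.39, adjusted p = 6.19e-05, with 51.2 and 78.6 CPM in controls and 10.1 and 14.5 CPM in mutants). It was also lower in osteolineage-like cells (-1.48, adjusted p = 5.67e-04) and endothelial-like cells (-0.85, adjusted p = 0.0289). Xist was present in all 4 libraries, with 282 and 516 CPM in control and 440 and 544 CPM in mutant mesenchyme (adjusted p = 0.312). The sex of the mice is not in the labels.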
